A study of Mus musculus with 6 samples.

How the data were processed

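Capture Hi-C maps of the mouse X-inactivation centre were analysed for day 0, day 4 and day 7 of embryonic stem cell differentiation and, at day 7, for cells given a scrambled or a Jpx-directed LNA. Per the labels' protocols, nuclei were digested with MboI, in situ Hi-C libraries were enriched with biotinylated RNA probes of 120 bp placed around MboI sites, and the captured DNA was amplified with 12 PCR cycles and sequenced as read pairs of 50 bp. The undifferentiated cells were grown on mouse feeder cells and were separated from them before differentiation, per the labels' protocols. The 1067 deposited probes ran from X 100154483 to 101264501 (mm9), 97.0% of them lay within 100 bp of a GATC (the MboI site) in the mm9 sequence, against 55.6% of random windows, and 22 of the 210 bins held no probe.

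The authors deposited each map as a symmetric table of signal values for pairs of 5 kb bins, and per the file headers the bins are those of mm9. Per the submitters' processing notes, cutadapt 1.2.1, Novoalign 3.00.02, HOMER 4.8 and Juicer 1.5.3 were used, with no role given for any of them. The filters, the removal of PCR duplicates, the way reads were assigned to an allele and the method that corrected the values are not given in the sources used here. Per the labels, the day 7 map of all reads came from control library 1, and each allelic map combined both libraries of its condition. The maps carry the names cas and mus, which are taken here as the 2 parental alleles. All deposited maps and the probe list were used.

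The deposited signal was not whole, but nearly every value could be written as a whole count divided by a factor for each of its bins. With a tolerance of 0.01, between 99.99% and 100.0% of the values above 0 in each map came out whole, and the factors followed the square root of the bin totals (slope 0.489, r = 0.999 at day 0, on logarithms). A correction of that kind evens out bin coverage only in part, so totals still differed between bins. Map totals of signal were close, at 175673, 177039 and 175900 for day 0, day 4 and day 7 and between 71306 and 71932 for the allelic maps, while recovered contacts between bins ranged from 23705 in depleted mus to 91391 at day 0. The design had foreseen intervals only if the values were counts. Since the unit was signal, intervals were instead drawn from the recovered counts. Poisson counts were redrawn 1000 times with the bin factors held fixed, the statistic was recomputed, and the 95% range of the draws was shifted so that their median equalled the measured value. The intervals leave out the spread between libraries and cultures, PCR duplicates and the error of the bin factors.

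Signal at separations of 10 kb or more was divided by the mean signal of its map at the same separation. A bin was left out where its total was under 0.25 of the median of the map in any map compared, which removed 3 bins from the maps of all reads and 4 from the allelic maps. Contacts were averaged within and between the 2 sides of a split at the middle of Xist, and shares of signal were given beside the means. The insulation score was the log2 of the mean signal between the 100 kb on each side of a bin over its median in the map. It was read at the promoters of Xist, Tsix and Jpx and at the lowest bin within 100 kb, and also at the middle of Cdx4 and Ftx, which were added after the data were examined. Locus contacts were the mean observed over expected signal between windows of 10 kb to each side of a promoter or gene body, and their percentile was taken among all rectangles of the same shape and separation. A ratio was not called where a map held 3 contacts or fewer for the pair. Windows of 30 kb by 30 kb at separations of 50 kb or more were compared with 100 pairs of maps simulated without a change. The day 7 allelic maps were compared as mus over cas, depleted over control on each allele, and the difference of those 2 effects. Gene positions came from the GENCODE annotation of the same build, where Jpx is listed as Enox and Ftx as B230206F22Rik. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.

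The groups, the statistics, the split, the 11 loci and the 10 alternatives were fixed before the data were examined. Chosen by that rule were the 27 pairs of the Xist, Jpx and Tsix promoters with the loci and, per comparison, the 3 highest and 3 lowest 30 kb windows that do not overlap, of which 1 is described. One of the 11 loci enters the counts of pairs but is not reported here. The other 28 pairs of the 11 loci were computed afterwards and appear in the closing observations. The alternatives were the median as the expected value, scaling to the map total, no filter on low bins, balancing to equal bin totals, flanks of 5 kb with insulation windows of 50 kb, flanks of 20 kb with insulation windows of 200 kb, a split at the Xist or at the Tsix promoter, separations of 50 kb or more, and bins with a probe only. A further filter, on bins whose recovered counts lay under 0.25 of the median of the map, was chosen after seeing the data, since a sparsely covered bin near the left end stood out in the mus maps. It left out 15 bins of the maps of all reads and 21 of the allelic maps.

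The method was tested on simulated data before use. Counts were recovered exactly for at least 99.9% of bin pairs in each of 7 simulated maps. These maps were made by dividing counts by the square root of the bin totals. The recovery uses the same relation to choose the unit of a bin, so maps corrected in another way were not tested. In 40 simulations per comparison of 27 pairs without a change, a mean of 1.68 pairs was called for day 4 over day 0, 1.28 for day 7 over day 0, 1.53 for mus over cas, 1.3 for depletion on mus and 1.85 for depletion on cas. Planted 2-fold changes were called in 99.0%, 98.5%, 91.0%, 80.0% and 92.5% of 200 cases in the same order. Smaller changes were not planted, so the power for them is not known. The lack of replicate maps limits all comparisons.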

Results

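The contacts of the X-inactivation centre, the part of the X chromosome that carries Xist and its regulators, were mapped by capture Hi-C in female mouse embryonic stem cells of a CAST/EiJ x 129S1 cross. In capture Hi-C, DNA that lies close together in the nucleus is ligated, ligation products of a chosen region are pulled out with RNA probes, and read pairs are counted per pair of bins. The cells were undifferentiated (day 0) or had been differentiated as embryoid bodies for 4 or 7 days. Cells at day 7 had been transfected with a locked nucleic acid (LNA) oligonucleotide, either scrambled (control) or directed against Jpx RNA (depleted), and were collected 8 hours later. Cells at day 0 and day 4 were not transfected, so day and transfection cannot be separated where day 7 is compared with day 0 or day 4. The 6 libraries were 1 of day 0, 1 of day 4, 2 of the day 7 control and 2 of the Jpx-depleted day 7 cells.

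The libraries were deposited as 7 maps of 210 bins of 5 kb, from X 100215001 to 101265000 on mm9. The maps of day 0, day 4 and day 7 control held all reads of 1 library each. The other 4 maps held the reads assigned to the cas or to the mus allele at day 7, with the 2 libraries of a condition already combined. No map had a replicate, so no difference was tested against the spread between libraries, and no p-value is given. Intervals are 95% intervals for counting error alone, and PCR copies of a ligation product are not independent counts. A pair, score or share is said to have risen, fallen or changed only where that interval excluded 0. The day 0, day 4 and day 7 control maps held 91391, 88600 and 90405 contacts between bins, as recovered from the deposited values. The allelic maps were shallower, with 37348 contacts in control cas, 27674 in control mus, 31830 in depleted cas and 23705 in depleted mus.

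The noncoding RNA genes lay in the middle of the region. Xist, whose RNA coats the X chromosome that is silenced, spans X 100655714 to 100678556 on the minus strand, with its promoter at 100678556. Tsix, the antisense repressor of Xist, runs on the plus strand from its promoter at 100626856 to 100680296, across the whole of Xist. Jpx, a noncoding RNA gene known as an activator of Xist and annotated as Enox, starts to the right of both at 100688895 and ends at 100701353. Ftx, annotated as B230206F22Rik, is another noncoding RNA gene, at 100756246 to 100819093. To the left of the Tsix promoter lay the protein-coding genes Tsx (100609806 to 100619919), Chic1 (100551815 to 100591431), Cdx4, a homeobox gene (100516737 to 100525931), and Nap1l2 (100379515 to 100381979). To the right of Ftx lay Zcchc13 (100825925 to 100827003) and Rlim, which encodes a ubiquitin ligase that promotes Xist expression (101152502 to 101176623, promoter at 101176623). Windows of 10 kb to each side of the promoter were used for Xist, Tsix, Jpx and Rlim, and the gene body with 10 kb to each side for the others. Neighbouring windows, such as those of Xist and Jpx or of Tsx and Tsix, shared bins, so their pairs were not independent.

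The first comparison asked how far the Tsix-side and the Xist-side parts of the region stayed apart during differentiation. The region was split at the middle of Xist, with the last base of the Tsix side at 100670000. At day 0, contacts between the sides made up 12.3% of the signal (95% interval 12.0 to 12.5). This share rose to 19.7% (19.4 to 19.9) at day 4 and stood at 18.9% (18.6 to 19.2) in day 7 control cells. The share is not corrected for separation, and signal at 500 kb or more also rose, from 5.30% at day 0 to 7.87% at day 4. Relative to the contact expected at equal separation, contacts between the sides rose from 0.748 at day 0 to 0.894 at day 4 and 0.893 at day 7. The log2 ratio was 0.26 (0.24 to 0.28) for day 4 over day 0 and 0.26 (0.24 to 0.27) for day 7 over day 0. Between day 4 and day 7 the log2 ratio of these contacts was -0.0014 (-0.02 to 0.01), while their share of the signal fell by 0.773 percentage points (-1.21 to -0.367), a fall whose interval held 0 at separations of 50 kb or more (-0.324, -0.876 to 0.244). The log2 ratio between these days had an interval below 0 with scaling to the map total (-0.058, -0.090 to -0.027) and with the split at the Tsix promoter. Each map was divided by its own mean at each separation, and shares add up to the whole. A rise between the sides therefore goes with lower values within them, which are not a separate result. Contacts within the Xist side, which holds Jpx, Ftx, Zcchc13 and Rlim, fell over the same time, from 1.35 times the expected value at day 0 to 1.15 at day 4 and 1.14 at day 7 (log2 ratios -0.24, -0.26 to -0.22, and -0.25, -0.27 to -0.23). Contacts within the Tsix side, which holds Nap1l2, Cdx4, Chic1, Tsx and Tsix, were at 1.04, 1.02 and 1.04 times the expected value, and both intervals against day 0 held 0, but their share of the signal fell from 33.1% at day 0 to 29.4% at day 4 (difference -3.73 percentage points, -4.30 to -3.13) and 29.9% at day 7 (-3.19, -3.76 to -2.63). Scaling to the map total in place of the expectation at equal separation raised the log2 ratios between the sides to 0.68 and 0.62.

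**Figure D1:**
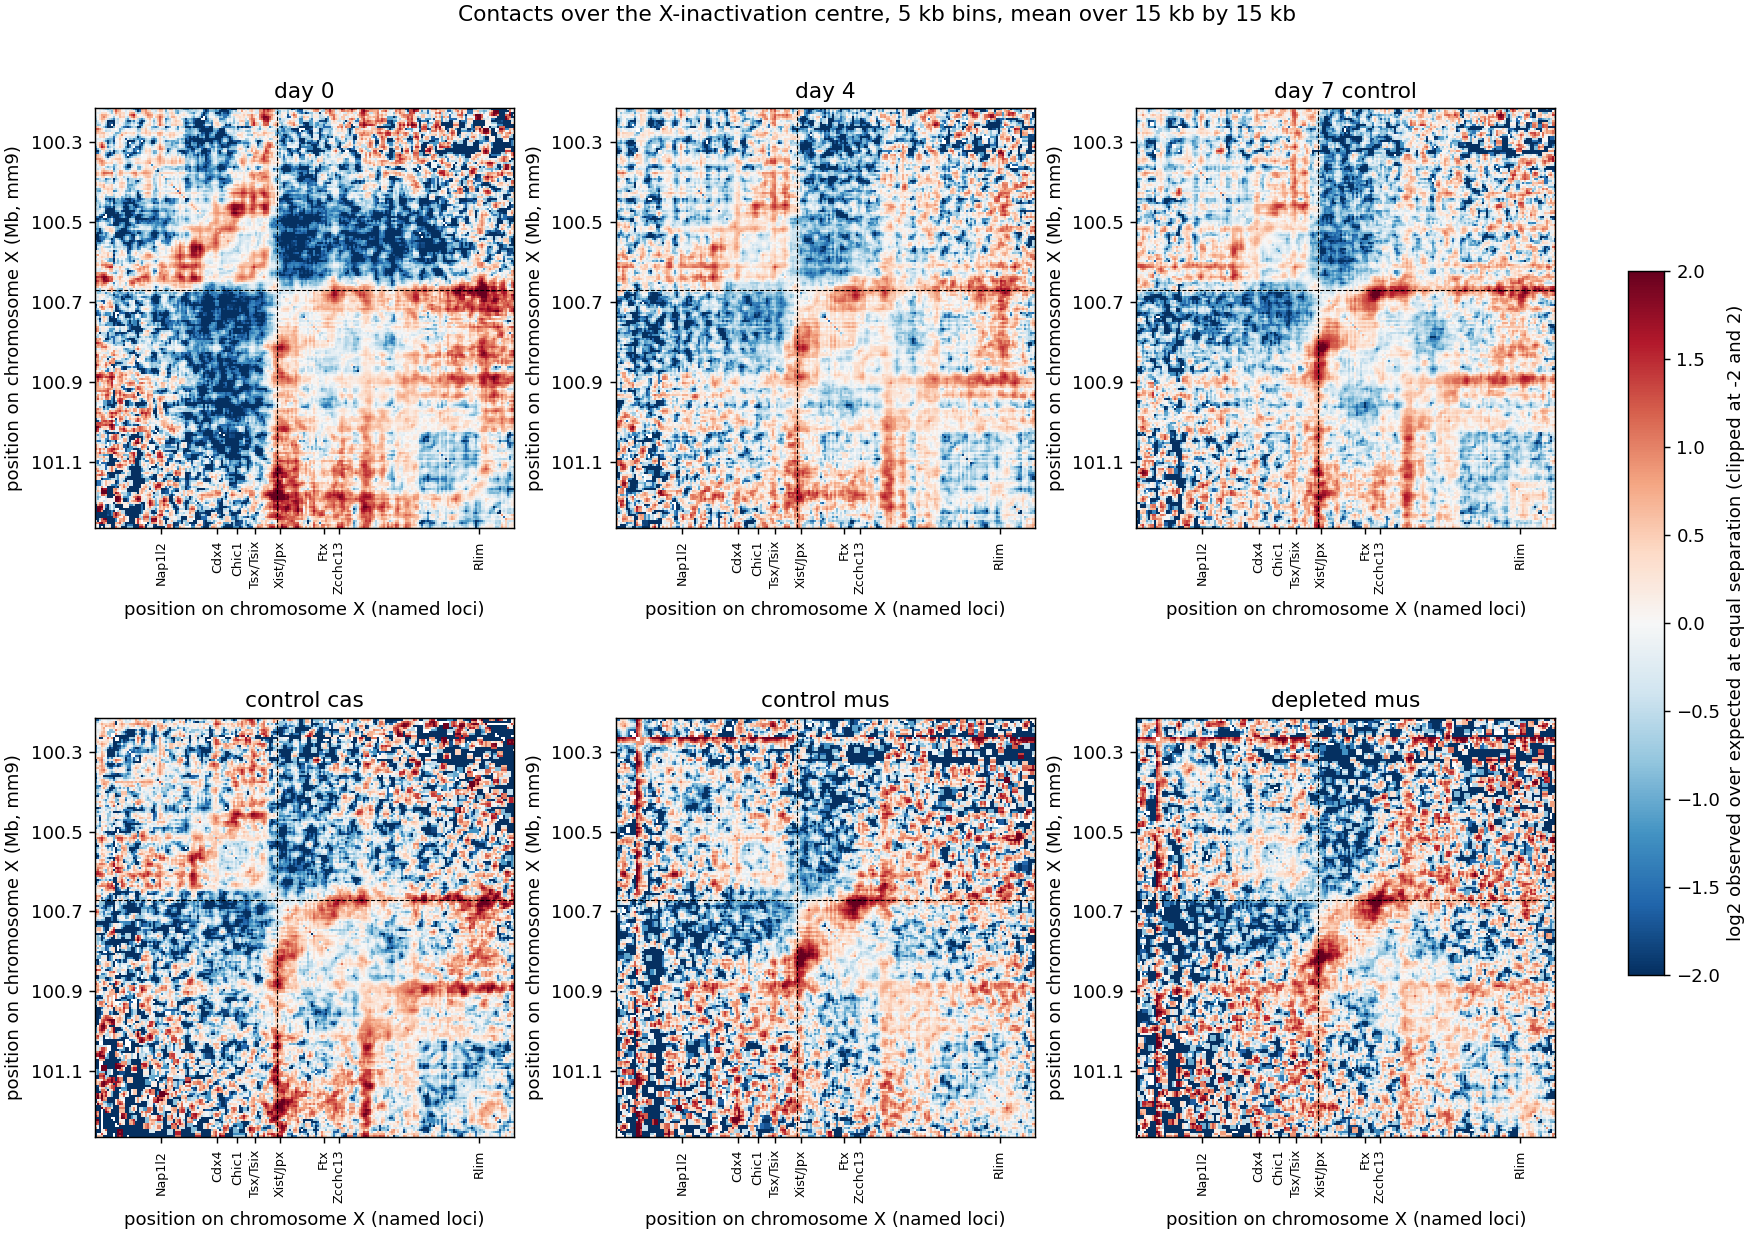
Maps of log2 observed over expected contact at equal separation over X 100215001 to 101265000 (both axes: position on X, mm9; colour clipped at -2 and 2; means over 15 kb by 15 kb) for day 0, day 4, day 7 control, control cas, control mus and depleted mus. The dashed lines mark the split at 100670000, and the blocks between the sides, at 0.748 times the expected contact at day 0, were paler at day 4 (0.894) and day 7 (0.893).

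The boundary between the sides was also read as an insulation score, the log2 of the contact between the 100 kb on each side of a bin over the median of the map, where low values mark a boundary. The Xist promoter scored -1.03 (-1.11 to -0.95) at day 0, -0.53 (-0.60 to -0.47) at day 4 and -0.66 (-0.73 to -0.59) in day 7 control cells. The score at Xist thus rose by 0.50 (0.39 to 0.59) from day 0 to day 4, the highest difference of the 170 bins measured. It lay 0.37 (0.26 to 0.48) above day 0 at day 7, a difference at percentile 84.1 of the bins, so other bins had risen more by then. At the Jpx promoter the score rose by 0.44 (0.35 to 0.53) by day 4 and by 0.31 (0.21 to 0.41) by day 7. At the Tsix promoter the difference was 0.02 (-0.08 to 0.11) at day 4, and by day 7 the score fell by 0.15 (-0.25 to -0.05). The lowest score of each map lay between the promoters of Tsix and Xist, at -1.21 (-1.29 to -1.12) in the bin starting at 100650001 at day 0, -0.79 (-0.87 to -0.71) in the bin at 100640001 at day 4 and -0.93 (-1.02 to -0.85) in the bin at 100650001 at day 7. Between day 4 and day 7 the score fell at Xist (-0.13, -0.22 to -0.03), Jpx (-0.13, -0.22 to -0.04) and Tsix (-0.17, -0.27 to -0.07). The size of the window and the smallest separation mattered. At separations of 50 kb or more the difference at Tsix was 0.22 (0.10 to 0.34) at day 4 and -0.028 (-0.15 to 0.09) at day 7. At day 4 the rises at Xist and Jpx had intervals above 0 with windows of 50 kb and of 200 kb, but the difference at Tsix was -0.21 (-0.33 to -0.08) with 50 kb and 0.22 (0.15 to 0.28) with 200 kb. With windows of 50 kb the difference from day 0 to day 7 was 0.14 (-0.02 to 0.29) at Xist, 0.06 (-0.06 to 0.20) at Jpx and -0.37 (-0.49 to -0.24) at Tsix. The falls from day 4 to day 7 were larger with these windows, at -0.29 (-0.41 to -0.15) for Xist and -0.35 (-0.48 to -0.22) for Jpx. With windows of 200 kb the differences from day 0 to day 7 were 0.59 at Xist, 0.57 at Jpx and 0.05 (-0.02 to 0.13) at Tsix. With these windows the later fall at Xist was lost (0.00062), and that at Jpx turned to a rise (0.065, 0.0067 to 0.11).

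**Figure D2:**
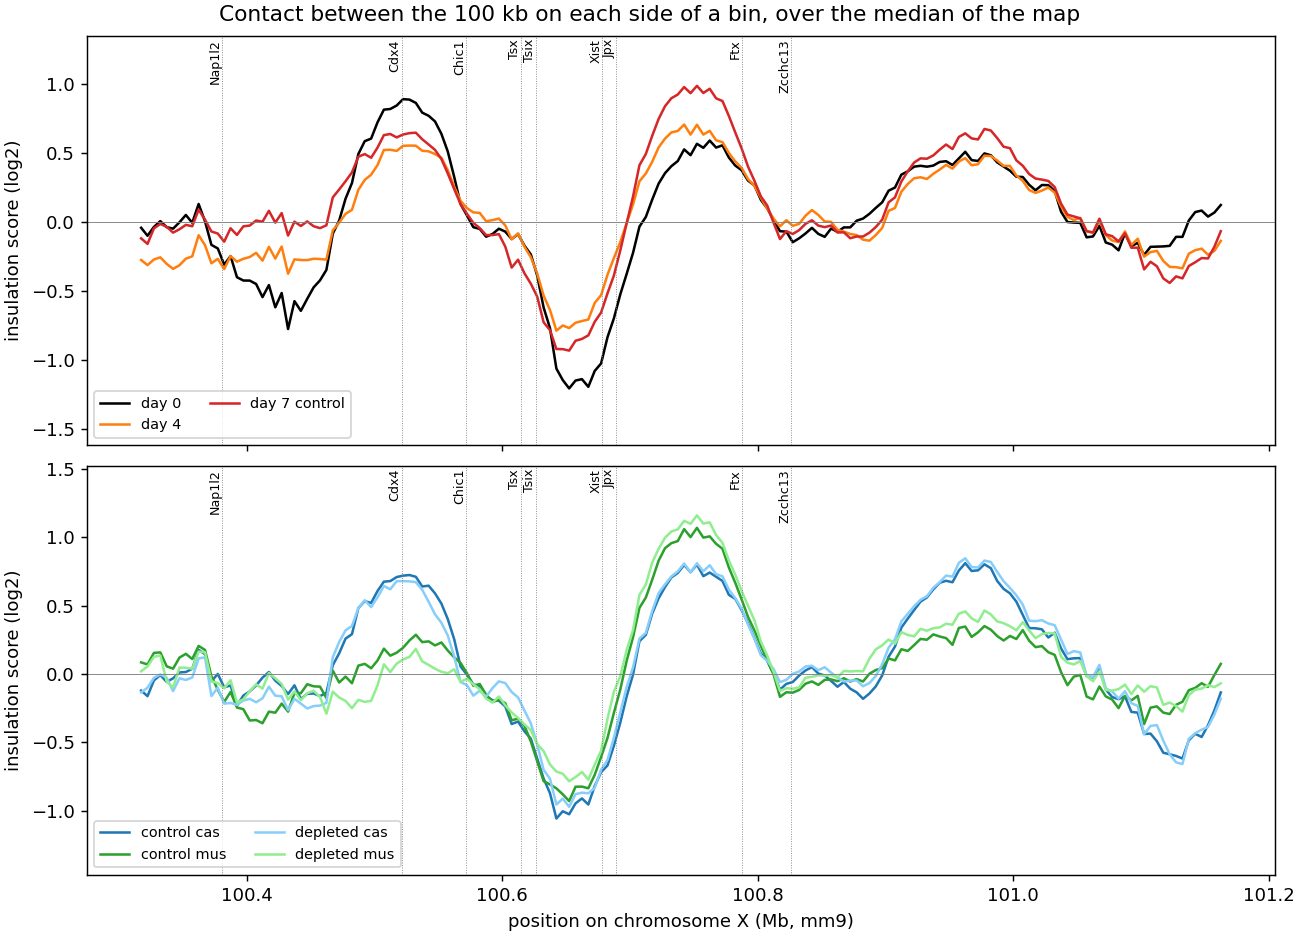
Insulation score (log2, vertical axis) of each 5 kb bin along X (Mb, mm9) for day 0, day 4 and day 7 control (upper panel) and for the 4 allelic day 7 maps (lower panel), with named loci as dotted lines. The minimum between Tsix and Xist lay at -1.21 at day 0, -0.79 at day 4 and -0.93 at day 7.

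The next comparison followed single contacts of the Xist, Jpx and Tsix promoters with the chosen loci, 27 pairs in all. From day 0 to day 4 contacts of these promoters with loci beyond the boundary rose, and contacts of Xist and Jpx with Rlim fell. Of the 27 pairs, 14 rose and 5 fell, against a mean of 1.68 pairs called in simulated maps without a change. Jpx-Cdx4 rose 2.29-fold (log2 1.2, 0.70 to 1.74), from 0.254 times the expected contact at day 0 (46 contacts) to 0.584 at day 4 (92 contacts). Of the 9 pairs that join Tsix or Jpx to a locus of the opposite side, 7 rose and none fell, among them also Jpx-Chic1 (log2 0.81, 0.47 to 1.18) and Tsix-Zcchc13 (0.67, 0.22 to 1.12). Xist, which sits at the split, rose in its contacts with Cdx4 (0.85, 0.41 to 1.24), Chic1 (0.58, 0.31 to 0.86), Tsx (0.36, 0.07 to 0.68) and Tsix (0.51, 0.18 to 0.86). On the Xist side, Xist-Rlim fell from 4.75 to 2.70 times the expected contact (log2 -0.82, -1.16 to -0.47), the highest value of all positions of the same shape in both maps. Jpx-Rlim (-0.69, -1.12 to -0.32) fell too, while Xist-Ftx (0.26, 0.15 to 0.37) and Jpx-Ftx (0.17, 0.05 to 0.28) rose. On the Tsix side, Tsix-Tsx fell (-0.26, -0.41 to -0.11). Each call was recomputed under up to 11 other settings, of which the 2 splits cannot alter a pair, and 10 of the 19 calls held in every one, among them Jpx-Cdx4, Jpx-Chic1 and Xist-Rlim. Halving the flanks to 5 kb, which leaves fewer contacts per pair, ended the calls of Xist-Cdx4, Xist-Tsx, Xist-Ftx, Jpx-Tsix, Jpx-Rlim, Tsix-Ftx and Tsix-Zcchc13, while Jpx-Ftx lost its call with the median as the expected value.

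By day 7 fewer of the 9 pairs that join Tsix or Jpx to the opposite side stood above day 0 than at day 4. Contacts of Xist and Jpx with Ftx had risen further. The lower number was not general, since of the 16 pairs across the boundary without Xist, Jpx or Tsix, 6 rose by day 4, and 7 rose and 1 fell by day 7. Against day 0, 11 of the 27 pairs rose and 5 fell, with a mean of 1.28 called in simulated maps without a change. Of the 9 pairs that join Tsix or Jpx to a locus of the opposite side, 5 rose and the intervals of 4 held 0. Those that rose included Jpx-Cdx4 (log2 0.78, 0.23 to 1.34), Tsix-Zcchc13 (0.63, 0.17 to 1.09) and Tsix-Ftx (0.60, 0.34 to 0.89). The intervals of Xist-Chic1 and Xist-Tsx, which had risen by day 4, held 0. Xist-Zcchc13 rose from 2.5 times the expected contact at day 0 to 3.69 at day 7 (log2 0.57, 0.40 to 0.74), and Xist-Ftx from 1.78 to 2.52 (0.50, 0.39 to 0.61). Xist-Rlim (-0.59, -0.92 to -0.29) fell, as did Tsix-Chic1 (-0.39, -0.55 to -0.24) and Tsix-Tsx (-0.34, -0.49 to -0.19). In all, 8 of the 16 calls held in every setting. Jpx-Tsix (0.45, 0.02 to 0.89) lost its call in 4 settings and stood at -0.29 with 5 kb flanks, and Xist-Cdx4 and Xist-Tsix lost theirs in 3 settings each. Jpx-Cdx4, Jpx-Zcchc13 and Tsix-Zcchc13 lost the call with 5 kb flanks and Xist-Rlim with the median as the expected value.

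Between day 4 and day 7, 4 pairs rose and 8 fell. The 4 were Xist and Jpx with Zcchc13 (log2 0.66, 0.48 to 0.83, and 0.49, 0.30 to 0.67) and with Ftx (0.24, 0.14 to 0.35, and 0.29, 0.19 to 0.39). The 8 were Xist-Jpx (-0.22, -0.41 to -0.04) and 7 contacts with Tsix-side loci, led by Jpx-Nap1l2 (-0.79, -1.60 to -0.09), Jpx-Chic1 (-0.58, -0.95 to -0.24) and Xist-Chic1 (-0.56, -0.86 to -0.28). Of the 12 calls, those of Xist-Zcchc13, Xist-Ftx, Jpx-Ftx, Xist-Chic1, Jpx-Chic1 and Tsix-Chic1 held in every setting, while Xist-Jpx and Xist-Tsx turned positive with 5 kb flanks (0.10 and 0.11). Jpx-Nap1l2 lost its call in 3 settings and Jpx-Cdx4 in 4. With the median as the expected value, 5 pairs rose and 5 fell. Calls of pairs in maps without a change were not simulated for this comparison.

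**Figure D3:**
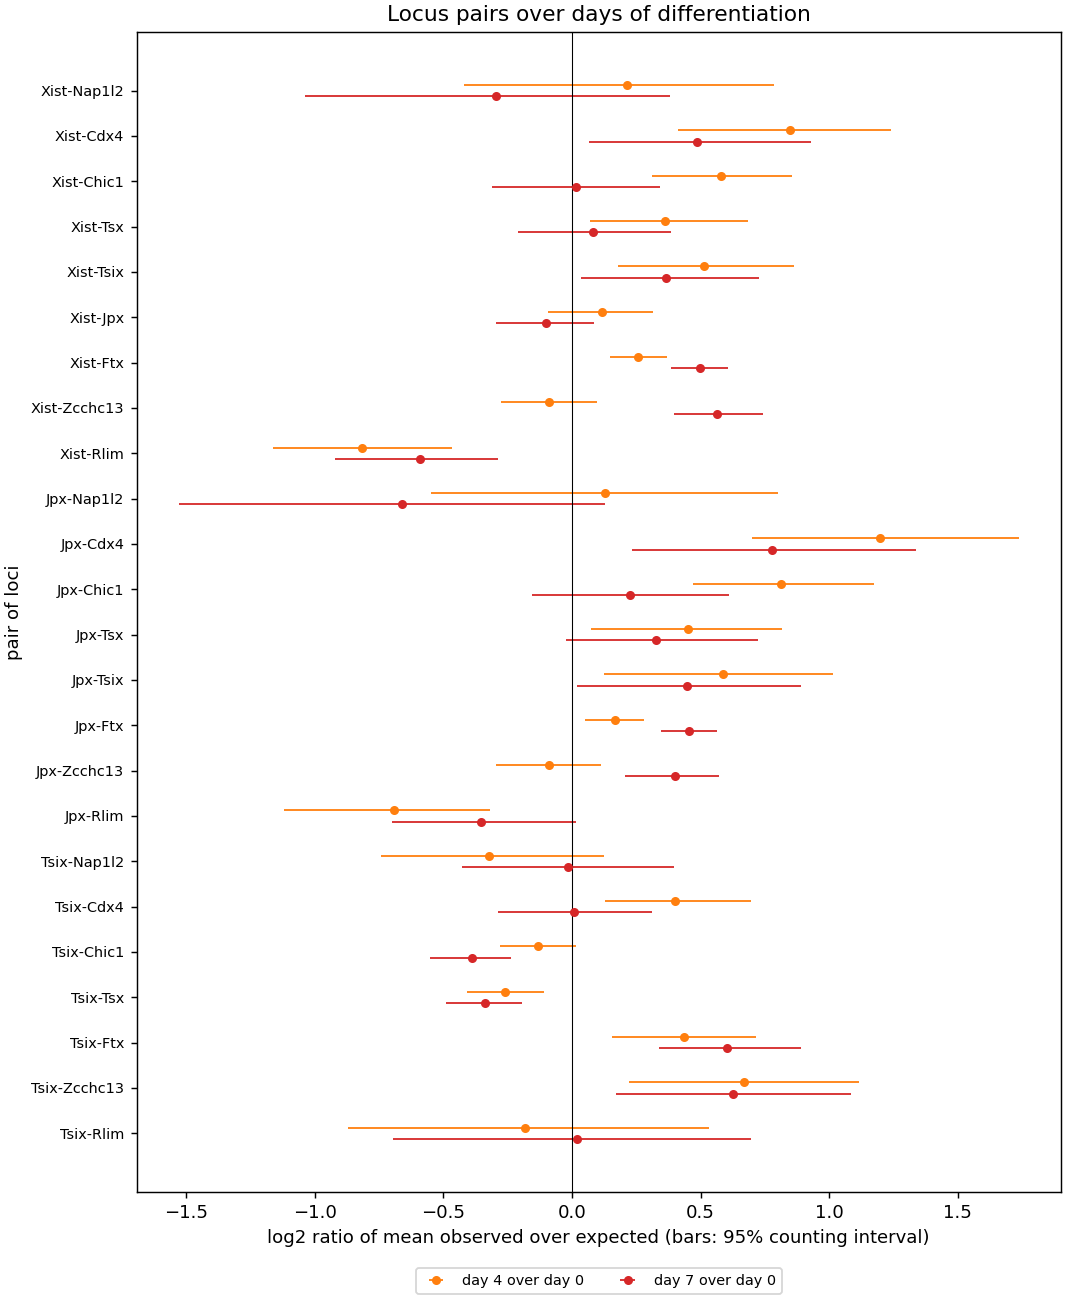
Log2 ratio of mean observed over expected contact (horizontal axis) for pairs of the Xist, Jpx and Tsix promoters with the named loci, day 4 over day 0 and day 7 over day 0, with 95% counting intervals as bars. Of the pairs shown Jpx-Cdx4 had risen most, at day 4 (1.2) and at day 7 (0.78).

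Windows of 30 kb by 30 kb at separations of 50 kb or more showed where in the region contacts moved most. Among the largest rises by day 4, Chic1 (100540001 to 100570000) gained contact with a window at 101035001 to 101065000, to the left of Rlim (log2 3.00, 1.74 to 5.47), with 4 contacts at day 0 and 37 at day 4. Changes beyond a log2 ratio of 1 in either direction took up 16.5% of windows at day 4 and 17.2% at day 7, against 2.34% and 2.18% in maps simulated without a change. From day 4 to day 7 the share was 1.68%, against 1.73% in simulated maps. The extreme of a ranking over 18843 windows is a biased estimate, and the highest value over the 100 simulations for day 4 over day 0 was 3.41.

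The allelic comparison at day 7 asked how the cas and the mus X chromosomes differed in control cells. Which allele was the inactive X is not given in the sources used here. Contacts between the sides were higher on mus than on cas, at 21.1% (20.6 to 21.7) against 17.4% (16.9 to 17.8) of the signal and at 0.958 against 0.839 times the expected contact (log2 0.19, 0.16 to 0.22). The difference in share was 3.75 percentage points, and 6.73 (5.82 to 7.85) at separations of 50 kb or more. Contacts within the Xist side and within the Tsix side were lower on mus (-0.16, -0.19 to -0.13, and -0.11, -0.17 to -0.05). Since each map was divided by its own mean at each separation, these lower values are tied to the higher value between the sides. The insulation score at Jpx was higher on mus by 0.24 (0.08 to 0.41), while the differences at Xist (0.11, -0.07 to 0.29) and Tsix (-0.02, -0.22 to 0.18) had intervals holding 0. With windows of 200 kb the differences were 0.57 (0.47 to 0.67) at Jpx, 0.49 (0.38 to 0.61) at Xist and 0.24 (0.10 to 0.36) at Tsix. Thinning the cas map to 74.1% of its contacts, the depth of mus, left the log2 ratio between the sides at 0.20 (0.18 to 0.22). This range is narrower than the counting interval at full depth, so it does not hold all counting error. A mean is not expected to shift with random thinning, so the value does not test depth as a cause.

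Of the 27 pairs, 7 were higher and 2 lower on mus, against a mean of 1.53 called in simulated maps without a difference. On mus, Xist made 2.84 times the expected contact with Ftx and 4.66 times with Zcchc13, against 1.87 and 2.91 on cas (log2 0.60, 0.42 to 0.77, and 0.68, 0.41 to 0.94). Jpx-Ftx (0.53, 0.36 to 0.70) and Jpx-Zcchc13 (0.57, 0.29 to 0.86) were higher on mus as well. Contacts of Rlim went the other way, with Xist-Rlim at 2.04 times the expected value on mus and 4.16 on cas (-1.03, -1.72 to -0.33; 26 and 67 contacts) and Jpx-Rlim at 1.28 and 3.39 (-1.41, -2.37 to -0.64; 16 and 54 contacts). Tsix-Zcchc13 (0.88, 0.24 to 1.56), across the boundary, and Xist-Cdx4 (1.00, 0.20 to 1.88) were also higher on mus. All 9 pairs differed in the same direction in the Jpx-depleted libraries, 6 of them with an interval excluding 0. The others were Xist-Cdx4 (0.29, -0.71 to 1.21), Xist-Rlim (-0.55, -1.32 to 0.20) and Jpx-Rlim (-0.79, -1.69 to 0.09). Xist-Ftx, Xist-Zcchc13, Jpx-Ftx and Jpx-Rlim kept their calls in every setting, and Tsix-Zcchc13, Xist-Cdx4, Xist-Rlim and Jpx-Zcchc13 lost theirs with 5 kb flanks, where 3 pairs were higher and 5 lower. Tsix-Zcchc13 also lost its call with the median as the expected value and with scaling to the map total, and Xist-Cdx4 with 20 kb flanks. The split of higher and lower pairs was 6 and 5 with the median as the expected value and 6 and 4 with scaling to the map total.

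The last comparisons asked whether depletion of Jpx RNA changed these contacts on each allele. The level of Jpx RNA is not measured by these maps, so the depletion itself is not checked here. On the mus allele no change was detectable at this depth in the contacts between the sides, at 21.4% (20.8 to 22.0) in depleted and 21.1% in control cells (log2 0.02, -0.0039 to 0.06). None of the 27 pairs of Xist, Jpx and Tsix changed, against a mean of 1.30 called in simulated maps without a change. The intervals of the better covered pairs were narrow, with Xist-Ftx at 0.06 (-0.12 to 0.23), Jpx-Ftx at 0.07 (-0.10 to 0.24) and Xist-Zcchc13 at -0.05 (-0.34 to 0.21), while pairs such as Jpx-Nap1l2 (6 contacts in control, 9 in depleted) and Jpx-Rlim (16 and 17) allowed changes of several fold. The score at the Jpx promoter rose by 0.15 with a lower bound of 0.00028, and the interval held 0 in all 7 of the other settings that can alter the score. Scores at Xist (0.05, -0.13 to 0.22) and Tsix (0.13, -0.07 to 0.33) had intervals holding 0. Windows beyond a log2 ratio of 1 made up 7.45%, against 6.97% in simulated maps. Flanks of 5 kb or of 20 kb each gave 2 changed pairs.

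On the cas allele contacts between the sides were 17.5% (17.0 to 17.9) in depleted and 17.4% in control cells (log2 0.02, -0.01 to 0.05). Of the 27 pairs only Jpx-Chic1 changed, 1.56-fold higher in depleted cells (log2 0.64, 0.09 to 1.31; 48 contacts against 41), against a mean of 1.85 pairs called in simulated maps without a change. The call of Jpx-Chic1 ended with the median as the expected value, with 5 kb flanks and with 20 kb flanks. Scores at Xist (0.02, -0.15 to 0.21), Jpx (0.06, -0.12 to 0.21) and Tsix (0.10, -0.09 to 0.29) had intervals holding 0. Windows beyond a log2 ratio of 1 made up 4.70%, against 5.11% in simulated maps.

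The depletion effect was then compared between the alleles, as the mus log2 ratio minus the cas log2 ratio. For contacts between the sides the difference was 0.0040 (-0.04 to 0.05). Of the 27 pairs the number with an interval excluding 0 was 1, and it was 0 with the median as the expected value and with scaling to the map total. The differences of the scores at Xist (0.03, -0.21 to 0.28), Jpx (0.10, -0.12 to 0.34) and Tsix (0.02, -0.25 to 0.32) had intervals holding 0.

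**Figure D4:**
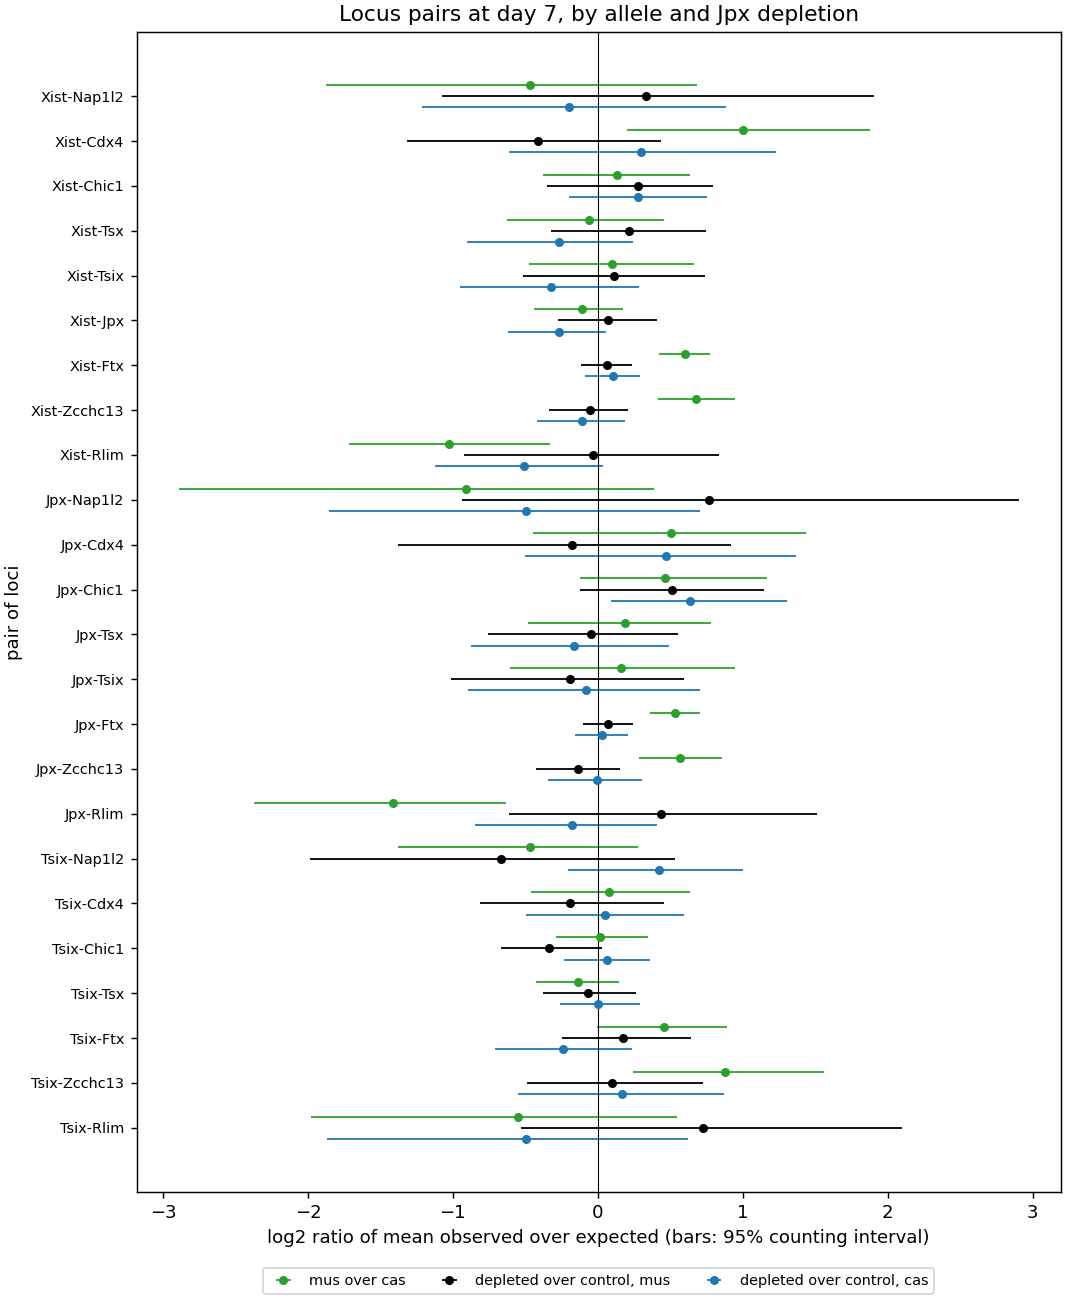
Log2 ratio of mean observed over expected contact (horizontal axis) for the same pairs at day 7, for mus over cas in control cells and for depleted over control on each allele, with 95% counting intervals as bars. Xist-Ftx (0.60) and Jpx-Rlim (-1.41) differed between the alleles, and under depletion only Jpx-Chic1 on cas (0.64) had an interval excluding 0.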

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

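All tests in this part were chosen after the results they bear on had been seen.

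The depletion effect of Jpx differed between the alleles for Chic1-Tsx, with a difference of -0.37 (-0.75 to -0.02) in log2 ratio. It stood out because the counting interval of the difference excluded 0. The difference was not tested against the spread between libraries, and among 55 pairs examined some 95% intervals exclude 0 by chance. Chic1-Tsx lost its call with scaling to the map total, with 20 kb flanks and at separations of 50 kb or more.

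Contacts within a bin, which enter no comparison, made up 5.58% (5.43 to 5.72) of recovered contacts at day 0, against 3.45% at day 4, 4.19% at day 7 and 3.70% to 4.37% in the allelic maps. They stood out as a measured signal outside the main comparisons. Of recovered contacts at 10 kb or more, 36.0% lay at 10 to 45 kb at day 0, against 31.8% at day 4 and 33.3% at day 7. The share was also high in control mus (35.1%) and depleted mus (35.9%). Contacts at 500 kb or more made up 4.13% at day 0, 5.83% at day 4 and 5.77% at day 7. The single day 0 library thus held more short-range contacts than those of day 4 and day 7, and the cause was not tested.

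Contacts between the Tsix side and the Xist side were higher at day 4 and day 7 than at day 0. Random ligation, which adds contacts evenly at all separations, may raise such contacts. If background were the whole cause, 9.71% of the day 4 signal would lie at separations of 500 kb or more, but 7.87% (7.64 to 8.09) did, against 5.30% at day 0. Background that matched this share would account for 4.29 of the 7.37 percentage points gained, so part of the rise stays open to it. Background spread evenly over all bins draws every pair towards the expected contact, and only 3 of the 19 pairs that changed by day 4 moved away from it. Transfection cannot account for the rise at day 4, with a log2 ratio of 0.26 over day 0, since neither was transfected. Its part in the day 7 value cannot be told, since day and transfection are not separated there. Differentiation, differences between single libraries, transfection for the day 7 value and, for part of the rise, random ligation stay open as explanations.

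Contacts between the sides were also higher on mus than on cas. For random ligation the test left the question open, with 8.50% (8.06 to 8.92) of control mus signal at 500 kb or more where 9.18% was predicted, and 8.72% (8.24 to 9.18) of depleted mus signal where 9.04% was predicted, so background and an allelic difference cannot be told apart for these totals. Of the 9 changed pairs, however, 6 moved away from the expected contact, which background spread evenly over all bins does not bring about. Among them were Tsix-Zcchc13, across the boundary, and Xist and Jpx with Ftx and Zcchc13. The latter lie within the Xist side and their windows share bins, so they are not independent. The count thus bears on those pairs and does not settle the cause of the higher total between the sides. Background that follows the coverage of the bins, which the correction of the values evens out only in part, was not tested. A chance difference of the control libraries is argued against by a log2 ratio of 0.20 (0.17 to 0.23) in the depleted libraries. After balancing the ratio was 0.20, which argues against uneven assignment of reads to alleles only where it acts as a factor of each bin. Other forms of uneven assignment cannot be judged, since the way reads were assigned is not given. The strain of the allele and its activity are possible explanations that the design does not separate.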

How the results depend on the processing

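The filter on recovered counts was chosen after seeing the data, and the other alternatives before. For each value below the cause of the shift was not tested. The log2 ratio of contacts between the sides for day 4 over day 0, 0.26 by the main method, stayed above 0 throughout, at 0.24 with the median as the expected value, 0.68 with scaling to the map total, 0.24 after balancing, 0.23 and 0.20 with the split at the Xist and Tsix promoters, 0.29 with probe bins and 0.30 with the filter on recovered counts. For day 7 over day 0 it was 0.62 with the map total, 0.18 with the split at Tsix, 0.29 with probe bins and 0.30 with that filter, and for day 7 over day 4 it was 0.020 with the median, -0.058 with the map total and -0.019 with the split at Tsix, the last 2 with intervals below 0, against an interval holding 0 by the main method. For mus over cas it was 0.13 with the median and 0.28 with the map total, and for depletion on cas -0.014 with the median.

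The insulation difference at the Xist promoter for day 7 over day 0 was 0.23 after balancing, 0.14 with smaller and 0.59 with larger windows, and for day 7 over day 4 it was 0.00062 with larger windows. At Tsix the difference for day 4 over day 0, 0.02 by the main method, was -0.21 with smaller and 0.22 with larger windows and 0.22 at separations of 50 kb or more, where for day 7 over day 0 it was -0.028. Larger windows also turned the difference at Jpx for day 7 over day 4 from -0.13 to 0.065 (0.0067 to 0.11), and for day 7 over day 0 that at Tsix from -0.15 to 0.050. Balancing gave -0.0026 at Ftx for day 7 over day 4 (0.14 by the main method), where smaller windows gave -0.025.

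With smaller windows 12 pairs changed from day 0 to day 4, against 19 by the main method. Pairs changed by depletion numbered 2 on mus with smaller and 2 with larger windows, against 0, and on cas 0 with the median, 2 after balancing and 3 with larger windows, against 1. The depletion effect differed between alleles for 0 pairs with the median, 0 with the map total and 3 with smaller windows, against 1. Smaller windows turned Xist-Tsx (0.11) and Xist-Jpx (0.10) for day 7 over day 4 and Jpx-Tsix (-0.29) for day 7 over day 0. Chic1-Rlim for day 7 over day 0 turned from -0.55 to 0.11 with the map total and 0.074 with larger windows, and Cdx4-Zcchc13 for mus over cas from 1.00 to -0.11 with the median.

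No paired analysis was possible because each allelic map combines the 2 libraries of its condition and each map of all reads holds 1 library, and leaving out a library was not possible for the same reason. The choice of expected value, the scaling and the split do not enter the insulation score, and the split does not enter the pairs. Separations of 50 kb or more left 25 of the 27 pairs. Depth limits the allelic maps most, where the 30 kb windows of unchanged simulated maps passed a log2 ratio of 1 in 5.11% to 6.97% of cases.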

Other observations

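The hypothesis tested in this part, and the loci and pairs described here, were chosen after the data had been seen.

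Among the 28 pairs of loci that do not involve Xist, Jpx or Tsix, Chic1 gained contact with Ftx and Zcchc13, and Ftx and Zcchc13 lost contact with Rlim. Chic1-Ftx (log2 0.61, 0.39 to 0.84) and Chic1-Zcchc13 (0.59, 0.20 to 1.00) rose by day 4. Nap1l2-Cdx4, within the Tsix side, rose 2.06-fold by day 4 (1.04, 0.57 to 1.54). By day 7 Zcchc13-Rlim (-0.70, -1.06 to -0.36) and Ftx-Rlim (-0.48, -0.71 to -0.27) fell. Of the 28 pairs, 8 rose and 3 fell by day 4, and 9 rose and 8 fell by day 7. On the mus allele Tsx-Zcchc13 (1.38, 0.86 to 1.99) and Tsx-Ftx (0.84, 0.45 to 1.22) were higher than on cas and Ftx-Rlim (-0.85, -1.40 to -0.38) lower, among 6 higher and 2 lower pairs. All 8 had an interval excluding 0 in the same direction in the depleted libraries. Under depletion of Jpx no interval of the 28 excluded 0 on mus. On cas Nap1l2-Rlim had too few contacts for a call, and the intervals of the other 27 held 0.

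The insulation score at Cdx4 was the highest of the 170 bins at day 0, at 0.89 (0.84 to 0.94), and fell by 0.34 (-0.42 to -0.26) by day 4, the lowest difference of any bin. The lowest score of the map, between Tsix and Xist, also moved towards 0, from -1.21 to -0.79, while Ftx stood at 0.37 and 0.39. A loss of contrast from random ligation was not tested for the insulation scores and stays open for the changes at Cdx4 and Xist. The difference of day 7 from day 0 was -0.26 (-0.34 to -0.18), and -0.12 with larger windows, -0.41 with smaller windows and -0.35 after balancing. The alleles differed there at day 7, with 0.72 (0.62 to 0.82) on cas and 0.19 (0.07 to 0.31) on mus (difference -0.53, -0.68 to -0.37). Ftx scored 0.47 on cas and 0.55 on mus (0.08, -0.04 to 0.20). Larger windows reduced the difference by day 4 at Cdx4 to -0.08 and that between the alleles to -0.17, while that at Ftx became 0.45 (0.36 to 0.53). In depleted cells the scores at Cdx4 were 0.68 on cas and 0.11 on mus, and no depletion effect at Cdx4 or Ftx had an interval excluding 0.

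A hypothesis is that the rearrangement over days lies more on the mus allele than on the cas allele. If so, windows that gain contact from day 0 to day 4 would be higher on mus than on cas at day 7. Over 475 windows of 30 kb, Spearman's rho between the 2 log2 ratios was 0.37. The windows are not independent, so one set was shifted along the region, and the highest rho of 34 shifts was 0.26. In the depleted libraries rho was 0.34, with a highest shifted value of 0.32. The day 7 over day 4 ratio, by contrast, gave -0.03 against the control libraries. Of the 55 pairs of loci, 10 changed from day 0 to day 4 and differed between the alleles, and 10 of these did so in the same direction, among them Tsix-Zcchc13 and Xist-Rlim. The result went the way the hypothesis predicts, but it adds little to results already given. Contacts between the sides were higher at day 4 than at day 0 and higher on mus than on cas. That shared pattern alone gives a rho above 0 and pairs with the same direction, and shifting the windows breaks it up. A background of random ligation that was higher at day 4 and on mus would also give a rho above 0, and allelic maps of day 0 and day 4 were not analysed here.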
